A study of Caenorhabditis elegans with 12 samples.

How the data were processed

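RNA of whole worms was sequenced as paired reads of 150 nt on a HiSeq4000 in 12 libraries: 4 with DMSO, 4 with bromhexine at 100 µM and 4 with genipin at 200 µM, each after 48 h, per the labels. Per the submitters' processing notes, the authors checked the reads with FastQC, aligned them to WBcel235 with STAR 2.7.11b and counted genes with RSEM 1.3.3. The deposited values are expected counts of RSEM, which divides reads that match several genes between them, and 2.06% of the values carry decimals. The release of the gene annotation and any trimming of reads are not given in the sources used here. All 46926 genes of the deposited table were found in the WBcel235 annotation used here (Ensembl release 115), which supplied symbols, positions and gene types. Each of the 12 columns of the table was joined to its sample by the labels.

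Expected counts were rounded to whole numbers and analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr on the 3 groups, which left 13695 genes, and libraries were scaled by TMM. One quasi-likelihood fit of the 12 libraries with the group as the only term gave the 3 contrasts: bromhexine against DMSO, genipin against DMSO and bromhexine against genipin. P was adjusted by Benjamini and Hochberg over all genes of a contrast, and a gene was called at an adjusted p under 0.05. Standard errors are the log2 fold change over the root of its F statistic. The biological coefficient of variation was 12.1%. Library totals ran from 20.3 to 28.1 M counts, so 3 counts, the floor used for a group at 0, are a small share of any library. For groups with 1 to 3 counts an exact 95% interval of the count ratio is given. Replicates of a group were compared by a chi-squared statistic per degree of freedom, which ran from 6.65 to 34.49, so no library was a copy of another of its group.

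The comparisons, tests, thresholds, alternatives, gene lists and the rule for named genes were chosen before the data were examined. The 41 lists cover xenobiotic metabolism (cytochrome P450, short-chain dehydrogenases, UDP-glucuronosyltransferases, glutathione S-transferases, P-glycoproteins and MRP transporters) and stress (SKN-1 reporters, antioxidant enzymes, DAF-16 induced and repressed genes, cytosolic heat shock, the unfolded protein responses of the endoplasmic reticulum and of mitochondria, hypoxia, metals, DNA damage and apoptosis). They cover immunity (intracellular pathogen response, PMK-1 genes, C-type lectins, lysozymes and caenopores, epidermal antimicrobial peptides) and metabolism (fatty acid oxidation, fatty acid synthesis and desaturation, glycolysis and gluconeogenesis, respiratory chain, one-carbon metabolism). They also cover proteostasis and translation (lysosome and autophagy, proteasome, cytosolic and mitochondrial ribosomal proteins) and tissues (vitellogenins, cuticle collagens, germline and oocyte, eggshell, sperm, histones, intestine, body wall muscle, pharynx, neurons, neuropeptides, hypodermis). Each list with at least 3 tested members was tested by camera in limma 3.58.1 on voom log2 CPM with the preset correlation of 0.01, adjusted over the lists of a contrast. Members past the test were counted over all genes and also with p adjusted over the list alone.

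For each compound against DMSO the named genes are the 10 largest increases and 10 largest decreases among called genes with a mean log2 CPM of at least 1 over the 12 libraries and no overlap between the groups, and for bromhexine against genipin the 5 largest. The abundance limit counts against genes that fell, since a fall lowers their mean. To these were added up to 3 called members with the smallest p of each list that was called or had at least 3 called members, 15 genes singled out in advance, and up to 5 genes called in opposite directions.

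The alternatives were DESeq2 1.42.0, limma voom, RLE and upper quartile scaling, TMM factors without tissue lists, no filter, a filter of 1 CPM in 4 libraries, the replicate number as a block, fits of only the 8 libraries compared, an adjusted p under 0.01, a minimum of 2-fold, and each library left out in turn. For lists they were camera with an estimated correlation and fry. After the data were seen, 3 more were added: genipin replicate 1 with its estimated share of bromhexine counts subtracted, summed hsp-16 copies, and split controls without genipin replicate 1. Shared controls were addressed by the 6 splits of the DMSO libraries between the compounds and by 20 simulations of unchanged groups with all 12 libraries drawn from the same gene means. A first version of that simulation kept the observed DMSO libraries, which left their error out, and it was replaced after its value (r = 0.0301) was seen. For the shared genes and r, 20 simulations added after the result was seen drew bromhexine libraries around their own gene means and DMSO and genipin libraries around the DMSO means. The 8 libraries of each comparison were also regrouped in all 35 ways.

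The procedure was tested on simulated data with known changes. All groups were drawn around the DMSO means, and 200 genes with a mean of at least 1 CPM were changed in the libraries of 1 compound. At 2-fold, 82.1% of changed genes were called with the bromhexine libraries changed and 97% with the genipin libraries changed. At 1.5-fold these shares were 52.2% and 61.2%, so many smaller changes would be missed. Of unchanged genes 0.068% and 0.061% were called. Neither run is modelled on a compound, so their difference does not describe the compounds, and far fewer genes were changed than were called with bromhexine. A simulated share of 3% bromhexine counts in genipin replicate 1 was estimated as 3.21% from 11 strongly induced genes and as 1.92% from 102 moderately induced ones. No library was left out of the main analysis. The raw reads were not used here, so trimming, alignment and the division of shared reads could not be repeated.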

Results

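Transcripts of whole young adult N2 hermaphrodites of Caenorhabditis elegans were counted after 48 h on plates with 100 µM bromhexine, 200 µM genipin or the solvent DMSO. Bromhexine is a mucolytic drug, and genipin is a plant compound known as a protein crosslinker and as an inhibitor of the mammalian uncoupling protein UCP2. Each of the 3 groups held 4 libraries, 12 in all, and the labels place them in 1 batch, with FUDR in the plates. The labels do not say that the 4 samples of a group were separate cultures, so every p below measures only the spread between these samples, which may be technical. The deposited table held expected counts for 46926 genes, with 20.3 to 28.1 M counts per library. Between 16893 and 17650 genes had a count in each library, and protein-coding genes took 98.24% to 99.27% of the counts. Ribosomal RNA took 1.084% of the counts in DMSO replicate 3 and 0.216% to 0.485% in the other 11. In all, 13695 genes passed the filter and were tested, with n = 4 libraries per group throughout. Errors are standard errors on log2 fold changes and standard deviations on CPM (counts per 1 M counts of the library). Intervals of count ratios and floors cover counting error only. The other intervals resample genes as if they were independent, which they are not, and cover no spread between libraries.

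The first principal component of log2 CPM carried 56% of the variance and set bromhexine apart. The bromhexine libraries lay between 42.7 and 65.2 on it, the DMSO libraries between -38.2 and -27.7, and the genipin libraries between -40.8 and -13.5, partly within the DMSO range. The coefficient of variation between libraries of a group beyond counting error was 12.1%.

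**Figure D1:**
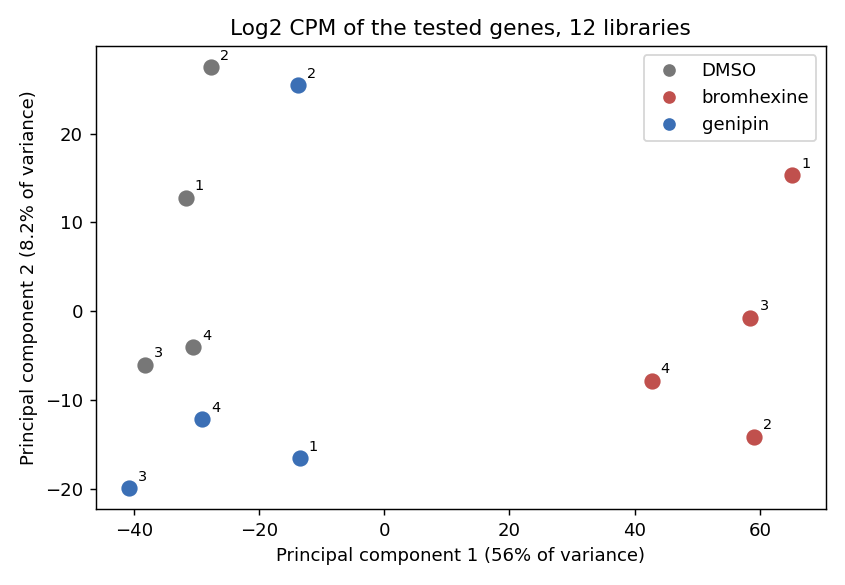
Each of the 12 libraries on the first 2 principal components of log2 CPM over 13695 genes (56% and 8.2% of the variance), colored by group and numbered by replicate. The 4 bromhexine libraries lie at 42.7 or above on the first component, and no DMSO or genipin library lies above -13.5.

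The comparison of bromhexine with DMSO asks which transcripts differ after 48 h on the drug. Some genes rose from near 0, and cytochrome P450 genes were among the largest increases, while cuticle collagens had the lowest median log2 fold change of the gene lists (-0.96). The cytochrome P450 gene cyp-35B2 rose from 0.464 ± 0.227 to 839 ± 48.2 CPM (SD, n = 4), a log2 fold change of 10.84 ± 0.82 (adjusted p = 1.48e-07, edgeR). Its neighbor cyp-35B3 had 0 counts in all 4 DMSO libraries and 365 ± 30.4 CPM with bromhexine, at least 12200-fold over the floor of 3 counts that 0 in the DMSO group allows (adjusted p = 1.36e-06). The collagen gene col-17 fell from 15.7 ± 7.99 to 0.141 ± 0.282 CPM, a log2 fold change of -6.93 ± 0.76 (adjusted p = 9.71e-06). Of the 13695 genes, 5581 passed an adjusted p of 0.05 in edgeR, 2602 higher and 2979 lower with bromhexine, and 1412 of them differed at least 2-fold, 382 higher and 1030 lower. The balance depended on the scaling, with 2034 higher and 3371 lower by upper quartile and 2785 and 2884 by RLE.

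The ranking of increases covers called genes with a mean log2 CPM of at least 1 over the 12 libraries whose 4 bromhexine libraries all lay above the 4 DMSO libraries. Genes under that abundance limit can have larger increases. Some of the genes that rose most lay side by side in the genome. The genes cyp-35B1 (WBGene00019472, start 3939032, end 3941237), cyp-35B2 (WBGene00019471, start 3942160, end 3944523) and cyp-35B3 (WBGene00019470, start 3945353, end 3947044) stand in a row on chromosome V of WBcel235. The protein-coding gene T10B5.8 (WBGene00020394, V, start 1842044, end 1844807) rose from 1.33 ± 0.112 to 1070 ± 98.9 CPM (log2 fold change 9.65 ± 0.83, adjusted p = 7.17e-07). Next to these stood Y73C8C.10 (10.92 ± 0.81, adjusted p = 1.14e-07), R09E12.9 (9.67 ± 0.79, adjusted p = 3.99e-07) and H25K10.4 (9.41 ± 0.51, adjusted p = 3.4e-09). The C-type lectin gene clec-68 (WBGene00018970, IV, start 3926417, end 3929105) rose by 8.83 ± 0.38 on the log2 scale, from 0.142 to 66.6 ± 16.7 CPM. The other 3 of the 10 largest increases in this ranking were R13D11.4 (7.66 ± 0.53), the P450 gene cyp-35A1 (7.42 ± 0.42, from 2.14 to 369 CPM) and the short-chain dehydrogenase gene dhs-23 (7.25 ± 0.36, from 1.16 to 178 CPM).

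**Figure D2:**
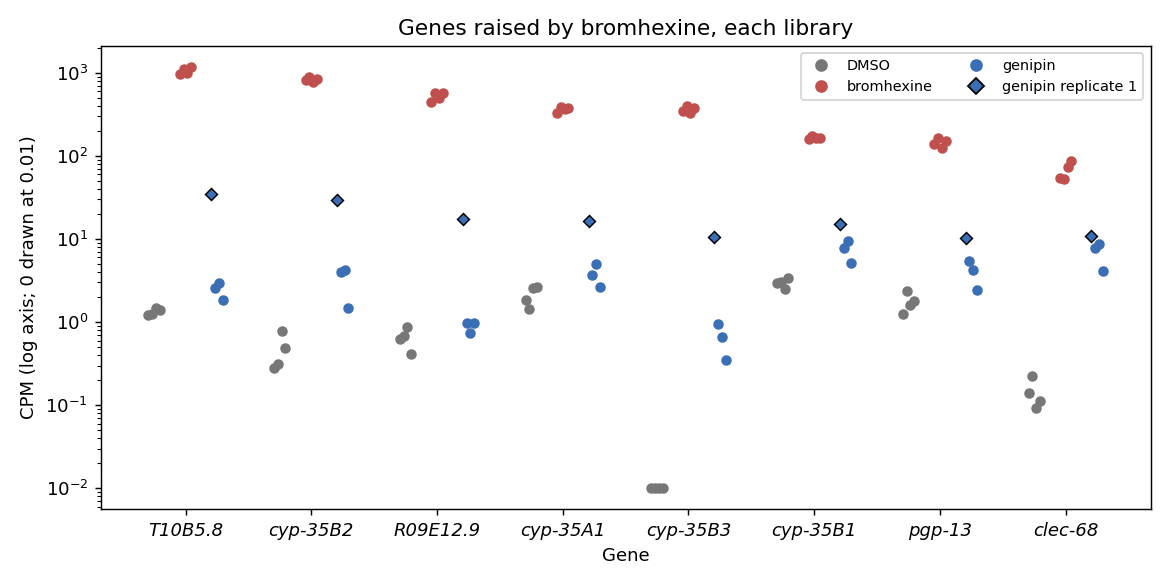
CPM of 8 genes in each of the 12 libraries on a log axis, with 0 drawn at 0.01 and genipin replicate 1 as outlined diamonds. The 4 bromhexine libraries lie above all others for every gene (cyp-35B2 at 781 to 898 CPM against 0.279 to 0.776 in DMSO), and genipin replicate 1 lies above the other genipin libraries (cyp-35B2 at 29.7 against 1.48 to 4.2).

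Among the lists of detoxification genes, 34 of 66 tested cytochrome P450 genes rose and 11 fell (35 and 11 adjusted over the list alone), with a median log2 fold change of 0.34 that stayed 0.34 with cyp-35B3 at its floor. The camera test called the list up (adjusted p = 2.18e-06, and adjusted p = 0.614 with an estimated correlation). Examples are cyp-35A5 (3.71 ± 0.13), cyp-35C1 (3.56 ± 0.14), cyp-34A9 (3.15 ± 0.11) and cyp-35B1, which rose 55.7-fold, from 2.98 to 167 CPM (adjusted p = 2.37e-10). Of 60 UDP-glucuronosyltransferases, enzymes that attach sugars to lipophilic compounds, 30 rose and 16 fell (31 and 17 over the list alone), among them ugt-36 (7.09 ± 0.36), ugt-9 (4.79 ± 0.23) and ugt-25 (2.75 ± 0.13). This list was called up (adjusted p = 0.000326, and 0.614 as the adjusted p with an estimated correlation). Glutathione S-transferases were not called as a list (adjusted p = 0.958), with 9 of 37 higher and 7 lower (9 and 9 over the list alone). Their median was -0.15, their mean 0.03 and the direction of the test up. Within it gst-5 rose 13.2-fold, from 31.1 to 410 CPM (3.72 ± 0.21), gst-33 by 2.32 ± 0.30 and gst-6 by 0.96 ± 0.13 on the log2 scale. P-glycoproteins and MRP transporters, which pump compounds out of cells, were not called either (adjusted p = 0.654), with 9 of 22 higher and 7 lower (9 and 8 over the list alone), a median of -0.02 and a mean of 0.22. Among the higher ones were pgp-13, from 1.76 to 146 CPM (6.39 ± 0.31), pgp-14 (3.16 ± 0.26) and pgp-3 (1.20 ± 0.11). In the other direction, pgp-8 stood at 2.57 to 5.7 CPM with bromhexine, against 12 to 21.6 in DMSO. Of 29 short-chain dehydrogenases 7 rose and 6 fell (the same over the list alone, adjusted p = 0.562), with dhs-18 at 0.97 ± 0.13 and dhs-16 at -2.88 ± 0.44.

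Stress genes divided by pathway. Of 14 genes known to rise under DAF-16, the transcription factor of reduced insulin signalling, 10 rose and 1 fell (the same over the list alone), with a median of 0.67. Among them were the mitochondrial superoxide dismutase gene sod-3 (1.65 ± 0.18), the lysozyme gene lys-7 (1.60 ± 0.18, from 279 to 847 CPM) and the metallothionein gene mtl-1 (1.49 ± 0.14). The list was called up (adjusted p = 0.00026, and adjusted p = 0.614 with an estimated correlation). Genes repressed under DAF-16 were not called as a list (adjusted p = 0.0672), although 5 of 9 fell and 2 rose (6 and 2 over the list alone), with dod-24 at -1.95 ± 0.21, dod-22 at -2.19 ± 0.33 and dod-17 at -1.50 ± 0.20. The vitellogenin genes vit-2 and vit-5, also in this list, rose. Antioxidant enzymes were not called (9 of 27 rose, 2 fell, the same over the list alone, adjusted p = 0.0625), with sod-1 at 0.69 ± 0.05 and the catalase gene ctl-2 at 0.93 ± 0.12. Genes that report SKN-1, the regulator of the oxidative stress response, were not called (3 of 12 rose and 4 fell, 3 and 5 over the list alone, adjusted p = 0.682, median -0.13, mean 0). The reporter gene gst-4 fell by 0.65 (± 0.16, adjusted p = 0.00636), and nit-1 (-0.95 ± 0.15) and gst-38 (-1.10 ± 0.21) fell too. In the other direction gst-5, also in this list, stood at 380 to 450 CPM with bromhexine against 23.2 to 44.2 in DMSO. Chaperones and folding enzymes of the endoplasmic reticulum were called down, with 8 of 18 lower and 1 higher (the same over the list alone), a median of -0.14 and hsp-3, an ER chaperone of the BiP family, at -0.57 ± 0.11. Their adjusted p was 0.0326, 0.614 as the adjusted p with an estimated correlation and 0.0502 without DMSO replicate 2. In that list dnj-27 fell by 0.68 and dnj-7 by 0.58. Cytosolic heat shock genes (5 of 13 rose, 0 fell, the same over the list alone, adjusted p = 0.284) and mitochondrial chaperones and proteases (6 of 12 rose, 1 fell, the same over the list alone, adjusted p = 0.127) were not called. Examples are hsp-70 (0.62 ± 0.12), sti-1 (0.25 ± 0.06), hsp-60 (0.39 ± 0.10), hsp-6 (0.29 ± 0.08) and atfs-1 (0.30 ± 0.07). The heat shock count includes hsp-16.48, whose reads are shared with a near-identical copy.

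Of the immune genes, 35 of 94 C-type lectins rose and 21 fell (39 and 22 over the list alone), among them clec-174 (5.02 ± 0.23) and clec-83 (1.19 ± 0.07). The list was called up with an adjusted p of 0.03, with an adjusted p of 0.614 with an estimated correlation, and with one of 0.0862 without bromhexine replicate 4. Antimicrobial peptides of the epidermis were called down, with 11 of 23 lower and 1 higher (13 and 1 over the list alone), for example cnc-4 (-1.19 ± 0.14), nlp-33 (-1.34 ± 0.16) and fipr-22 (-1.10 ± 0.22). Their adjusted p was 0.00429, and their adjusted p with an estimated correlation was 0.614. Of 10 genes of the PMK-1 p38 immune pathway 4 rose and 4 fell (the same over the list alone, adjusted p = 0.666, median -0.12, mean 0.21), with irg-6 at 3.37 ± 0.13, irg-4 at 1.73 ± 0.10 and C17H12.8 at -1.60 ± 0.14. The kinase gene pmk-1 itself fell by 0.75 (± 0.10, adjusted p = 6.21e-05). Lysozymes and caenopores were not called (2 of 32 rose and 11 fell, the same over the list alone, adjusted p = 0.495), with spp-12 at 3.41 ± 0.29 and spp-17 at -0.98 ± 0.13.

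Several metabolic and proteolytic gene groups rose by small amounts. Of 33 proteasome subunits 22 rose and 0 fell (24 and 0 over the list alone), with a median of 0.22 and pas-6 at 0.32 ± 0.08, pbs-4 at 0.27 ± 0.06 and rpn-12 at 0.25 ± 0.05. Of 22 enzymes of glycolysis and gluconeogenesis 14 rose and 2 fell (17 and 2 over the list alone), with gpi-1 at 0.75 ± 0.05, pck-2 at 0.65 ± 0.08 and fbp-1 at 0.40 ± 0.05. Of 31 genes of fatty acid synthesis and desaturation 13 rose and 3 fell (the same over the list alone), with the elongases elo-6 at 1.49 ± 0.12 and elo-2 at 0.93 ± 0.08 and with let-767 at 0.80 ± 0.06. These 3 lists were called up, with adjusted p of 4.15e-06, 0.00026 and 0.0015, and 0.614 for each as the adjusted p with an estimated correlation. Fatty acid oxidation was not called (11 of 40 rose and 8 fell, 12 and 8 over the list alone, adjusted p = 0.0871), although hacd-1 (2.03 ± 0.09), ech-7 (1.29 ± 0.11), acox-1.4 (1.28 ± 0.13) and the acyl-CoA synthetase gene acs-2 (0.55 ± 0.10) rose. Of 79 lysosome and autophagy genes 26 rose and 15 fell (26 and 16 over the list alone), with the lipase gene lipl-5 at 1.46 ± 0.07, the cathepsin gene cpr-3 at 1.57 ± 0.09 and the aspartyl protease gene asp-1 at 1.06 ± 0.07, from 1390 to 2910 CPM. The list stood at an adjusted p of 0.0498 (0.7 as the adjusted p with an estimated correlation), and leaving out any of 6 libraries ended the call, with an adjusted p of 0.104 without bromhexine replicate 4. Cytosolic ribosomal proteins, with 5 of 76 higher and 3 lower (1 and 2 over the list alone), stood at the same adjusted p of 0.0498 (0.865 as the adjusted p with an estimated correlation, 0.331 without DMSO replicate 3). Examples are rpl-7A at 0.33 ± 0.08, rpl-11.2 at -0.43 ± 0.10 and rpl-41.1 at -0.84 ± 0.19. Subunits of the respiratory chain and ATP synthase were not called (9 of 72 rose and 6 fell, 5 and 3 over the list alone, adjusted p = 0.817), with atp-1 at 0.33 ± 0.08, asb-1 at 0.31 ± 0.07 and sdhb-1 at 0.20 ± 0.05.

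**Figure D3:**
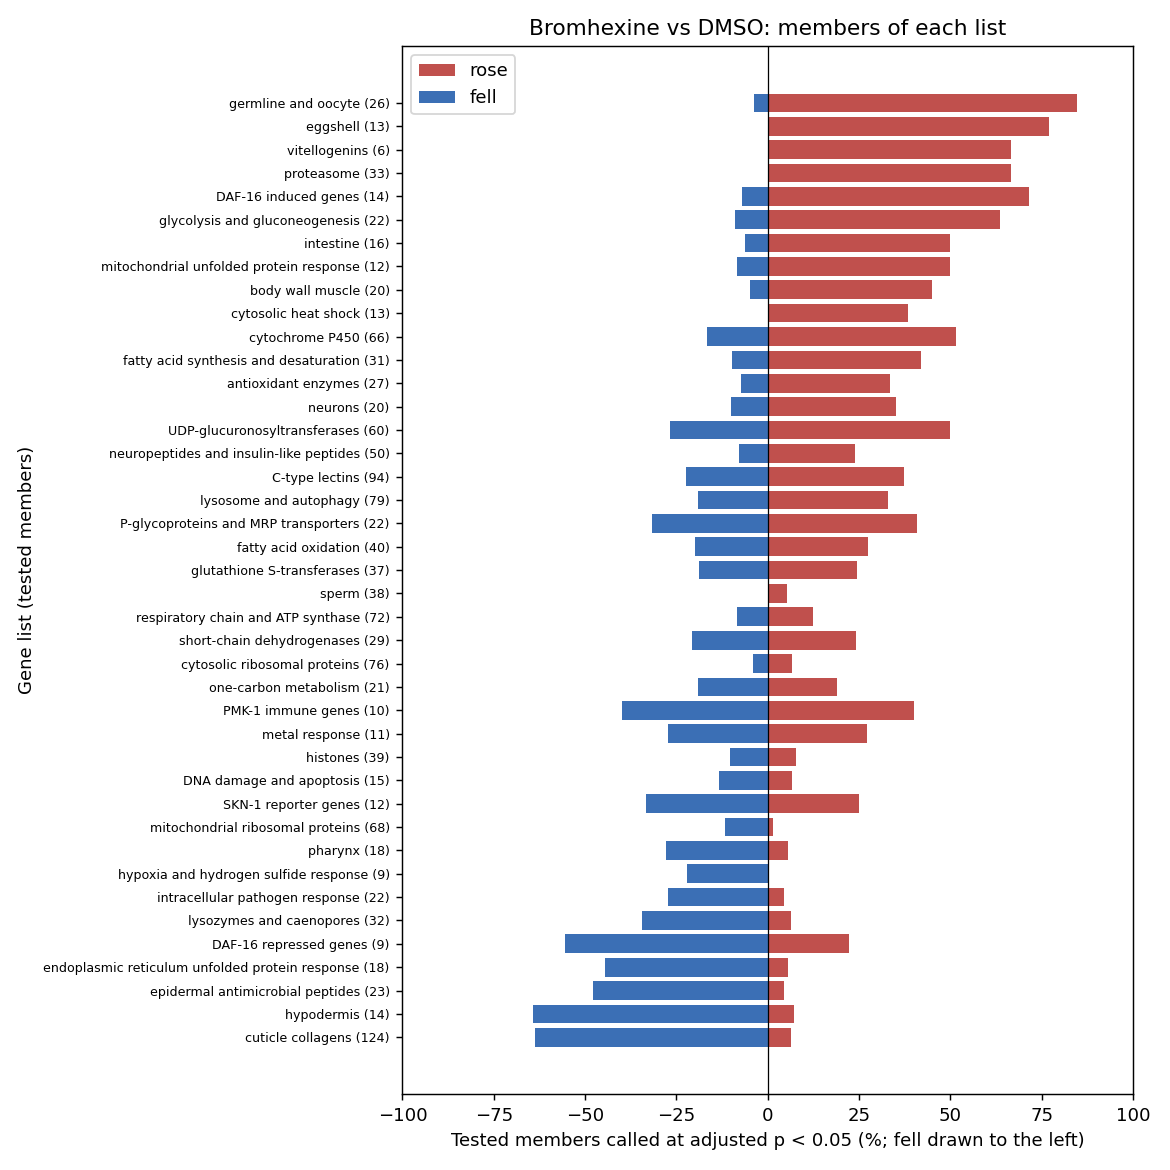
Share of the tested members of 41 gene lists that rose (to the right) or fell (to the left) with bromhexine against DMSO. Of the cuticle collagens 79 of 124 fell, and of the cytochrome P450 genes 34 of 66 rose.

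Transcripts of the germ line, eggs and yolk were modestly higher. Of 26 germline and oocyte genes 22 rose and 1 fell (23 and 1 over the list alone, median 0.32), with glh-4 at 0.44 ± 0.10, pie-1 at 0.41 ± 0.08 and pgl-1 at 0.36 ± 0.08. Of 13 eggshell genes 10 rose and 0 fell (12 and 0 over the list alone), with chs-1 at 0.54 ± 0.12, egg-3 at 0.51 ± 0.09 and cpg-1 at 0.44 ± 0.12. The camera test called both up, with adjusted p of 4.83e-06 and 0.000326 and with an adjusted p of 0.614 for both with an estimated correlation. The mean log2 CPM of the germline list was 8.65 to 8.74 in bromhexine replicates 1 to 3 and 8.44 in replicate 4, against 8.21 to 8.44 in DMSO. The vitellogenins, yolk proteins made in the intestine, held the most abundant transcripts in the table. Of the 6 vitellogenins 4 rose and 0 fell (the same over the list alone), with vit-6 at 0.66 ± 0.11 (from 23600 to 37300 CPM), vit-2 at 0.53 ± 0.11 and vit-5 at 0.49 ± 0.12. Their adjusted p was 0.0307, with 0.661 as the adjusted p with an estimated correlation, 0.0741 without DMSO replicate 2 and 0.0955 without bromhexine replicate 4. Of 16 intestinal markers 8 rose and 1 fell (8 and 2 over the list alone, adjusted p = 0.00697, and adjusted p = 0.614 with an estimated correlation), with the esterase gene ges-1 at 1.44 ± 0.08 and cpr-1 at 1.56 ± 0.14. Of 20 sarcomere genes of body wall muscle 9 rose and 1 fell (10 and 1 over the list alone), with the myosin gene myo-3 at 1.55 ± 0.15, ttn-1 at 0.98 ± 0.22 and unc-87 at 0.68 ± 0.10. That list had an adjusted p of 0.002, an adjusted p of 0.661 with an estimated correlation and one of 0.056 without bromhexine replicate 4. Neuropeptide and insulin-like peptide genes were called up with 12 of 50 higher and 4 lower (the same over the list alone, adjusted p = 0.0304, and adjusted p = 0.614 with an estimated correlation), with flp-9 at 0.87 ± 0.17. Leaving out bromhexine replicate 2 or 4 took the adjusted p of that list to 0.0648 or 0.0617. In the opposite direction the insulin-like peptide gene ins-19 (WBGene00002102, II, start 3126037, end 3126441) fell 21.9-fold to 0.567 ± 0.244 CPM (-4.45 ± 0.32, adjusted p = 6.83e-08), and ins-37 fell by 1.68. Pan-neuronal genes were not called (7 of 20 rose and 2 fell, the same over the list alone, adjusted p = 0.155), with egl-21 at 0.70 ± 0.10, ida-1 at 0.62 ± 0.11 and unc-119 at -0.74 ± 0.14. Sperm genes were called up with 2 of 38 higher (ssp-10 at 1.52 ± 0.38 and spe-44 at 0.35 ± 0.09, the same over the list alone), an adjusted p of 0.0111 and an adjusted p of 0.736 with an estimated correlation. Their mean log2 CPM varied from -2.05 to 0.92 between libraries, and the adjusted p was 0.0711 without DMSO replicate 4 and 0.056 without bromhexine replicate 4.

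Genes of the cuticle and of the epidermis that makes it were lower. Of 124 tested cuticle collagens 79 fell and 8 rose (84 and 8 over the list alone), with a median log2 fold change of -0.96 (adjusted p = 5.16e-11, and adjusted p = 0.614 with an estimated correlation). The list held 4 of the 10 largest decreases by the rule set in advance: col-17 (WBGene00000606, II, start 4866436, end 4867576), dpy-4 (-5.24 ± 0.55), col-167 (-4.12 ± 0.43) and col-117 (-3.91 ± 0.70). The members with the smallest p were col-12 (-3.63 ± 0.33), col-73 (-7.41 ± 0.67) and col-90 (-5.14 ± 0.50). Others of the 10 largest were the cuticlin gene cut-2 (-4.80 ± 0.50), F41F3.3 (-5.53 ± 0.51), ZK180.5 (-5.19 ± 0.44), ram-2 (-4.36 ± 0.40) and Y47D7A.13 (-4.24 ± 0.30). The collagen genes dpy-13 (370-fold lower, 95% interval of the count ratio 126 to 1800, with 3 counts in all in the bromhexine libraries, adjusted p = 3.31e-06) and dpy-5 (-6.0), chosen after their values were seen, lay under the abundance limit of that rule. Of 14 epidermal genes other than collagens 9 fell and 1 rose (the same over the list alone, median -0.79, adjusted p = 0.000881, and adjusted p = 0.614 with an estimated correlation), with noah-1 at -1.03 ± 0.16, grd-3 at -0.96 ± 0.14 and dpy-6 at -1.29 ± 0.21. Pharyngeal genes were not called (1 of 18 rose and 5 fell, 0 and 5 over the list alone, adjusted p = 0.601, median 0.07, mean -0.52). Within them pha-4, the transcription factor gene of pharyngeal identity, fell by 0.94, pqn-74 fell by 2.06, and abu-8 was 59.2-fold lower (95% interval of the count ratio 16 to 494).

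**Figure D4:**
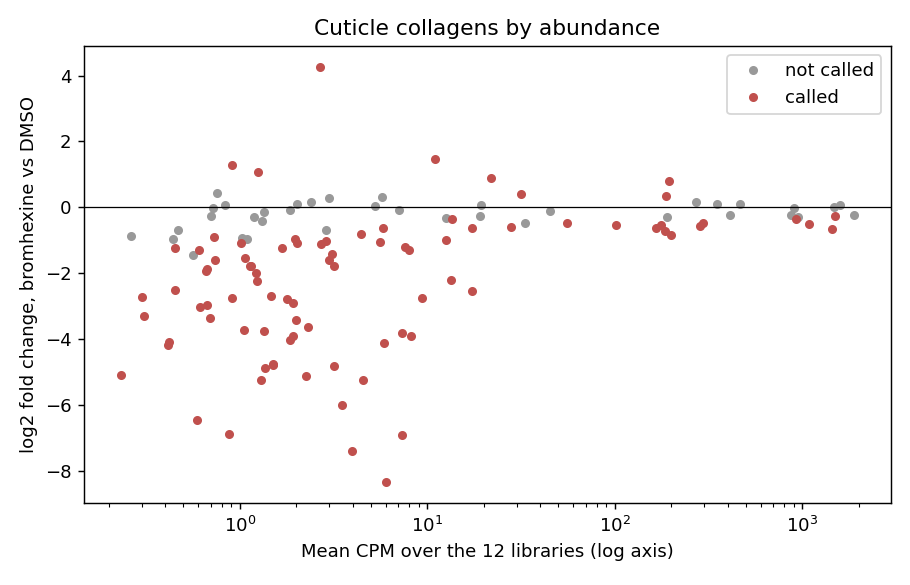
Log2 fold change of the 124 tested cuticle collagens with bromhexine against DMSO over their mean CPM in the 12 libraries (log axis), with genes past the test in red. The 94 collagens under 20 CPM had a median of -1.57, and the 24 at 100 CPM or above had a median of -0.27.

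Of 15 genes singled out in advance, 5 did not pass the test with bromhexine: the uncoupling protein gene ucp-4 (0.05 ± 0.09, adjusted p = 0.701), the ER chaperone gene hsp-4 (-0.08 ± 0.05, adjusted p = 0.201), the small heat shock gene hsp-16.2 (-0.16 ± 0.14, adjusted p = 0.374), the desaturase gene fat-7 (-0.29 ± 0.14, adjusted p = 0.112) and skn-1 (0.10 ± 0.06, adjusted p = 0.215). The transcription factor gene daf-16 rose by 0.37 ± 0.08 (adjusted p = 0.0021). The 4 bromhexine libraries did not overlap the 4 DMSO libraries for 4913 genes (35.9% of those tested, where chance gives 2.86%), and 4373 of these passed the test. Of the 41 lists 16 were called up and 4 down, 0 of them by camera with an estimated correlation, where 3 lists had an unadjusted p under 0.05, and 25 by fry. Leaving out 1 library left 4239 calls (without DMSO replicate 3) to 6254 (without bromhexine replicate 4), and 9 lists called up without bromhexine replicate 4.

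The comparison of genipin with DMSO asks the same of the second compound, and here 5 of 13695 genes passed the test. The C-type lectin gene clec-68 rose 53.9-fold, from 0.142 ± 0.0583 to 7.9 ± 2.79 CPM (log2 fold change 5.75 ± 0.42, adjusted p = 9.7e-06), with 4.16 to 10.8 CPM in the genipin libraries and at most 0.224 in DMSO. The P450 gene cyp-35B1 rose 3.12-fold, from 2.98 ± 0.375 to 9.41 ± 4.32 CPM (1.64 ± 0.25, adjusted p = 0.0317). C07D8.6 (WBGene00015565, X, start 7341509, end 7342780), a gene of the aldo-keto reductase family, rose 1.32-fold, from 221 ± 6.3 to 293 ± 16 CPM (0.40 ± 0.06, adjusted p = 0.0398). With the replicate number as a block cyp-35B1 (1.61 ± 0.25, adjusted p = 0.0514) and C07D8.6 (0.40 ± 0.07, adjusted p = 0.128) were not called: the fold changes barely moved, and the block leaves 6 residual degrees of freedom instead of 9. The P450 gene cyp-13A5 (WBGene00011672, II, start 9798277, end 9800362) fell 1.75-fold, from 25.9 ± 1.47 to 14.8 ± 1.36 CPM (-0.80 ± 0.12, adjusted p = 0.0237).

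The fifth call, the small heat shock gene hsp-16.48 (WBGene00002019, V, start 9088131, end 9088617), is uncertain because its reads are shared with the near-identical hsp-16.49. Its log2 fold change was 7.65 ± 0.60 (adjusted p = 1.19e-05) with genipin and 7.07 ± 0.61 with bromhexine. The 2 copies summed gave -0.21 ± 0.14 (adjusted p = 0.994) and -0.32 ± 0.14 (adjusted p = 0.0884), and 4 genes remained called with genipin.

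Of the cyp-35B cluster only cyp-35B1 was called with genipin over all 4 libraries. In genipin replicate 1 the genes that bromhexine raised most stood far above the other 3 genipin libraries: cyp-35B2 at 29.7 CPM against 1.48 to 4.2, cyp-35B3 at 10.5 against 0.35 to 0.937 and T10B5.8 at 34.6 against 1.87 to 2.99. Without that library 6 genes were called, among them cyp-35B1 (1.3 ± 0.17, adjusted p = 0.00888) and, named after their values were seen, cyp-35B2 (2.78 ± 0.37, adjusted p = 0.00888) and cyp-35B3 (at least 21.1-fold over the floor of 3 counts, adjusted p = 0.0159). The counts of cyp-35B3 in genipin replicates 2, 3 and 4 were 22, 14 and 9, and 0 in every DMSO library. T10B5.8 stood at 0.88 ± 0.18 (adjusted p = 0.209) and the transporter gene pgp-13 at 1.21 ± 0.25 (adjusted p = 0.28) without that library, and C07D8.6 was no longer called (adjusted p = 0.137).

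At the level of lists, camera called 8 of 41 up and 7 down with genipin, and 0 with an estimated correlation (lowest adjusted p = 0.425, with 3 lists at an unadjusted p under 0.05) and 0 by fry (2 at an unadjusted p under 0.05). Body wall muscle was called up, with all 20 log2 fold changes above 0, a median of 0.29 and an adjusted p of 1.67e-13 (0.447 as the adjusted p with an estimated correlation), although 0 of 20 members passed over all genes and 2 over the list alone. Its mean log2 CPM was 6.06 to 6.53 in the genipin libraries and 5.74 to 6.34 in DMSO. Cuticle collagens were called down (adjusted p = 2.36e-08, and adjusted p = 0.447 with an estimated correlation), with a median of -0.13 and 0 of 124 members past the test over all genes, and 34 lower and 1 higher over the list alone. Subunits of the respiratory chain and ATP synthase (median -0.07, adjusted p = 1.2e-08, and adjusted p = 0.425 with an estimated correlation) and mitochondrial ribosomal proteins (median -0.07, adjusted p = 1.33e-05, and adjusted p = 0.447 with an estimated correlation) were called down by small amounts. Vitellogenins were called up (all 6 above 0, median 0.24, adjusted p = 7.4e-06, and adjusted p = 0.447 with an estimated correlation), as were P-glycoproteins and MRP transporters (median 0.14, adjusted p = 6.12e-05, and adjusted p = 0.425 with an estimated correlation, 2 higher over the list alone).

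The other 9 list calls with genipin each ended when 1 of at least 3 libraries was left out. Cytochrome P450 genes (8 higher and 1 lower over the list alone, adjusted p = 0.0307) and UDP-glucuronosyltransferases (adjusted p = 0.0132) were called up, with adjusted p of 0.377 and 0.417 without genipin replicate 1. In that library the mean log2 CPM of the P450 list was 2.36, against 1.76 to 2.02 in the other genipin libraries and 1.72 to 1.84 in DMSO. PMK-1 immune genes (adjusted p = 0.025), eggshell genes (0.0307) and pan-neuronal genes (0.0141) were called up, with adjusted p of 0.444 without genipin replicate 3, 0.885 without genipin replicate 2 and 0.0828 without DMSO replicate 3. Cytosolic heat shock genes were called down (adjusted p = 0.00956, median -0.12 but mean 0.20 through hsp-16.48), with an adjusted p of 0.162 without DMSO replicate 1. Cytosolic ribosomal proteins (adjusted p = 0.0012), sperm genes (0.00018) and pharyngeal genes (0.00668) were called down, with adjusted p of 0.967 without DMSO replicate 1, 0.115 without genipin replicate 4 and 0.115 without DMSO replicate 2. The adjusted p of these 9 lists with an estimated correlation was between 0.447 and 0.865.

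None of the other 14 genes singled out in advance passed the test with genipin. The uncoupling protein gene ucp-4 (WBGene00006729, V, start 9334298, end 9336671) was at 27.5 CPM with genipin and 31.4 with DMSO (-0.19 ± 0.09, adjusted p = 0.994). The values were 0.05 ± 0.16 for gst-4, 0.01 ± 0.19 for sod-3, -0.02 ± 0.05 for hsp-4, 0.03 ± 0.08 for hsp-6, 0.08 ± 0.14 for mtl-1 and -0.56 ± 0.14 for hsp-16.2 (adjusted p = 0.466). They were -0.18 ± 0.10 for acs-2, 0.07 ± 0.14 for fat-7, 0.24 ± 0.11 for vit-2, -0.09 ± 0.18 for lys-7, 0.01 ± 0.06 for skn-1, 0.05 ± 0.08 for daf-16 and -0.13 ± 0.10 for pmk-1. In edgeR 671 genes had an unadjusted p under 0.05, where chance alone gives 685, and 426 genes did not overlap between the groups (3.1%, where chance gives 2.86%). DESeq2 called 30 genes and limma voom 2, C07D8.6 and cyp-13A5, and leaving out any DMSO library or bromhexine replicate 3 left 2 calls, clec-68 and hsp-16.48.

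The direct comparison of bromhexine with genipin asks where the 2 treatments as given differ, since the doses differ (100 and 200 µM) and the compounds are not analogs. Cytochrome P450 genes were higher as a group with bromhexine than with genipin and cuticle collagens lower by camera, though not with an estimated correlation (adjusted p = 0.507 for both). Y73C8C.10 (7.15 ± 0.59), cyp-35B3 (6.90 ± 0.60), H25K10.4 (6.71 ± 0.40), R09E12.9 (6.71 ± 0.63) and T10B5.8 (6.68 ± 0.68, 1070 ± 98.9 against 10.5 ± 16 CPM) were the 5 largest increases by the rule set in advance, with its abundance limit. The 5 largest decreases by that rule were col-17 (-5.59 ± 0.80), ins-19 (-4.53 ± 0.32), pud-3 (-4.40 ± 0.27, adjusted p = 1.74e-08), F41F3.3 (-4.06 ± 0.54) and dpy-4 (-3.99 ± 0.58). Genes under the limit fell further, such as dpy-13 (157-fold lower than with genipin, 95% interval of the count ratio 53.4 to 764). In edgeR 4728 genes passed the test, 2057 higher and 2671 lower with bromhexine, and 1259 of them differed at least 2-fold.

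Of 66 P450 genes 32 were higher with bromhexine and 14 lower (35 and 15 over the list alone, adjusted p = 1.89e-07, and adjusted p = 0.507 with an estimated correlation). Examples are cyp-35B1 (4.16 ± 0.21), cyp-35A5 (3.28 ± 0.13) and cyp-34A9 (2.99 ± 0.11). UDP-glucuronosyltransferases were called up (28 of 60 higher and 13 lower, adjusted p = 0.000409, and adjusted p = 0.567 with an estimated correlation). The other 3 lists of detoxification genes were not called: short-chain dehydrogenases (7 of 29 higher and 5 lower, adjusted p = 0.202), glutathione S-transferases (9 of 37 higher and 8 lower, adjusted p = 0.709), with gst-5 at 3.54 ± 0.21, and P-glycoproteins and MRP transporters (5 of 22 higher and 7 lower, adjusted p = 0.732), with pgp-13 at 4.70 ± 0.27 and pgp-8 at -2.13 ± 0.21. Of the 124 cuticle collagens 73 were lower and 8 higher (84 and 8 over the list alone, adjusted p = 4.1e-09, and adjusted p = 0.507 with an estimated correlation), with col-98 at -0.89 ± 0.10 and col-36 in the other direction at 4.52 ± 0.43. The epidermal genes (10 of 14 lower and 0 higher, adjusted p = 0.000103, and adjusted p = 0.507 with an estimated correlation) and proteasome subunits (22 of 33 higher and 0 lower, adjusted p = 8.69e-08, and adjusted p = 0.551 with an estimated correlation) also differed. Body wall muscle (2 of 20 higher and 1 lower, adjusted p = 0.55) and vitellogenins (1 of 6 higher and 1 lower, adjusted p = 0.395) were not called between the compounds. Of the genes singled out in advance, gst-4 (-0.69 ± 0.16) and pmk-1 (-0.62 ± 0.10) were lower and acs-2 (0.73 ± 0.10) higher with bromhexine. For ucp-4 (0.23 ± 0.09, adjusted p = 0.0518), fat-7 (-0.36 ± 0.14, adjusted p = 0.0573), vit-2 (0.28 ± 0.11, adjusted p = 0.0547), skn-1 (0.09 ± 0.06) and hsp-4 (-0.07 ± 0.05) the test was not passed. The call on hsp-16.2 (0.40 ± 0.14, adjusted p = 0.0447) ended in 9 of the 12 fits that leave out a library. Of the 41 lists 17 were called up and 5 down, 0 with an estimated correlation (lowest adjusted p = 0.507, with 1 list at an unadjusted p under 0.05) and 24 by fry. With upper quartile scaling 1476 genes were higher and 3024 lower, against the 2057 and 2671 with TMM. Leaving out 1 library left 3301 calls (without genipin replicate 3) to 5672 (without bromhexine replicate 4), and 1301 higher genes without genipin replicate 3.

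The overlap of the 2 comparisons with DMSO was limited to the genes called with genipin, which were 5, or 4 with the hsp-16 copies summed. All 5 of them (clec-68, cyp-35B1, C07D8.6, hsp-16.48 and cyp-13A5) passed the test with bromhexine in the same direction, and 0 in the opposite one. With the copies summed, where hsp-16.48 was called in neither comparison, the other 4 were shared. Lists drawn independently would share 0.76 higher and 0.218 lower genes. Shared DMSO libraries make directions agree, so 20 simulations kept the bromhexine means, left genipin unchanged and shared the simulated DMSO libraries. There, of the 5 genes with the smallest genipin p, 1 to 4 (2.55 on average) were called with bromhexine in the same direction, and 1 to 3 (2.05) of the 4 smallest. At an unadjusted p under 0.05 in both comparisons, edgeR gave 366 genes in the same direction and 43 in opposite directions, against 234 to 302 and 101 to 145 in these simulations, which draw each gene independently. DESeq2 gave 25 and 3 at its adjusted p. These observed counts include genipin replicate 1, which stood far above the other genipin libraries for the genes that bromhexine raised most. The simulations hold no such library, and the counts at an unadjusted p were not repeated without genipin replicate 1. With the DMSO libraries split between the compounds, 2 genes were shared in every split.

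Across the 13695 genes the log2 fold changes of the compounds correlated with a Pearson r of 0.474. The simulations with genipin unchanged gave 0.141 (0.117 to 0.167), and those with both compounds unchanged, in which nothing but shared control error and noise remains, 0.498 (0.467 to 0.537). The covariance was 0.117, against 0.0311 and 0.033 on average in these simulations. With split controls r was 0.223 to 0.392 and the covariance 0.071 to 0.116, and without genipin replicate 1 the splits gave an r of 0.106 to 0.242 and a covariance of 0.0325 to 0.0724. Genes are not independent replicates, so no p is given for r.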

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

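Of the tests here, those on a small exposure to bromhexine, on index hopping and on the hsp-16 copies were chosen after the result was seen, as were the interval on abundant collagens, the spread between libraries for moderately induced genes and the splits by replicate number. In each group of 4 libraries the sample farthest from the others was looked at, for library measures, list means and named genes. Of 648 such groups 56 held a sample far from the other 3, where chance alone gives about 32.4.

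Genipin replicate 1 stood apart for transcripts that bromhexine raised: T10B5.8 at 34.6 CPM, cyp-35B2 at 29.7, R09E12.9 at 17.5, cyp-35A1 at 16.36, R13D11.4 at 11.8, cyp-35B3 at 10.5, dhs-23 at 6.91, Y73C8C.10 at 6.78 and H25K10.4 at 2.63. It also stood apart for cpr-1 (436), acs-2 (104.3), ges-1 (33.4) and col-36 (0.535). From 11 genes that bromhexine raised from near 0, this library held 3.26% of the bromhexine level, against -0.00352% to 0.179% in the other 7 libraries without bromhexine. Under a fixed share of bromhexine RNA or reads alone, 90 moderately induced genes were to give at most 6.53%. They gave 11.2%, 3.45 times the share from strong ones (interval 2.74 to 4.21, from resampling the genes of this library). The other libraries ran from -4.76% to 5.06% (SD 4.32), and the margin over the bound was close to that SD. The value argues against a fixed share alone but cannot exclude it. Index hopping at an equal rate into all libraries was excluded, by the same values that set this library apart. The median share in the other 7 libraries was 0.00177 times that of this one. Genipin replicates 2 to 4, which lay above the DMSO libraries at 0.0963% to 0.179%, had 0.0295 to 0.0549 times the share of genipin replicate 1. Hopping from bromhexine libraries into genipin replicate 1 alone was not tested. A small exposure of this culture, or a stronger response of it to genipin, stayed open: the log2 ratios to bromhexine had an SD of 0.704 (0.101 to 1.1), since 10 of the 11 genes lay at 2.8% to 4.47% and clec-68, also at 6.91 CPM in genipin replicates 2 to 4, at 16%. With the level of those 3 libraries subtracted the SD was 0.326 (0.105 to 0.484), under the 0.5 that such a response was expected to reach. That bound was set after the values were seen, and the 11 genes are the most strongly induced ones, so the evenness excludes neither.

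The near-identical small heat shock genes hsp-16.48 and hsp-16.49 moved against each other between groups. In the 4 DMSO libraries hsp-16.48 had 18, 1, 1 and 0 counts and hsp-16.49 had 1672, 1133, 1231 and 1325. With bromhexine they had 731, 451, 338 and 984 against 0, 451, 675 and 328, and with genipin 1027, 792, 1347 and 568 against 0, 0, 4 and 568. The largest change of the summed copies was 0.32 in size on the log2 scale, which is consistent with reads divided differently between the copies rather than with a change of either. In bromhexine replicate 2 (451 and 451) and genipin replicate 4 (568 and 568) the copies held equal counts, as an even division of reads would give. A sequence difference between the cultures of the groups would also move reads from one copy to the other. The division varied within groups, from 731 and 0 to 338 and 675 with bromhexine, which argues against such a difference as the only source. Whether it contributed was not tested here.

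Cuticle collagens were lower with bromhexine. The choice among the 4 scalings was excluded as the cause, since the highest median over them was -0.95. All 4 take most genes as unchanged, so a shift common to them was not tested, and the fall is relative to other transcripts. Fewer larvae among the collected worms met both values set in advance for it: collagens at 100 CPM or more had a median of -0.27 (24 genes, 11 lower and 2 higher), above -0.3, and those under 20 CPM one of -1.57 (interval -2.25 to -1.11, 94 genes, 66 lower and 4 higher), below -1. It stayed undecided because an interval added after these values were seen (-0.51 to -0.01) spans the first. FUDR, which the labels place in the plates, is known to stop progeny from developing. A direct lowering of collagen transcription in adults stayed open.

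For bromhexine against DMSO, with the replicate numbers ignored, a split of the samples by chance could be excluded as the source of the calls. The real grouping, with 5581 calls in edgeR, was the only 1 of 35 with as many, and the highest other split gave 0. For genipin against DMSO chance could not be excluded as the source of the number of calls, since 3 of 35 splits, the real one with 5 calls included, gave as many and the highest other gave 13. A number of calls does not test single genes, such as clec-68 (4.16 to 10.8 CPM with genipin, at most 0.224 in DMSO). The 7 other splits with 1 library of each replicate number on each side gave 0 calls each. If the numbers pair the samples, which stays open, such splits are too few for a share under 0.05 in each of the 3 comparisons. For bromhexine against genipin, with the numbers again ignored, a split of the samples by chance could be excluded (1 of 35, 4728 calls). The highest other split, which exchanges bromhexine replicate 4 with genipin replicate 2, gave 2373. A share of 1 of 35 is the smallest that these splits can give. The labels do not say that the samples of a group were separate cultures. Regrouping the samples therefore cannot exclude a chance difference between single cultures.

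Bromhexine replicate 4 had 17561 genes with a count and 14.19% of its counts in its 10 most abundant genes, and stood apart in the mean log2 CPM of vitellogenins (13.97) and hypodermis genes (3.86). Its genes far from the other bromhexine libraries were vit-6 (40180 CPM), vit-2 (36090), his-72 (522), rpl-11.2 (368), pie-1 (101), mtl-2 (39.1), pha-4 (25.3), nit-1 (19.1) and sams-5 (10.8). Bromhexine replicate 1 stood apart in heat shock genes (6.33), col-17 (0.564) and ssp-10 (1.03), replicate 2 in gst-10 (15.9), and replicate 3 in ZK180.5 (0.579), abu-8 (0.0891) and col-36 (5.26). The heat shock mean includes hsp-16.49, which had 0 counts in bromhexine replicate 1 against 451, 675 and 328 in the other bromhexine libraries. Its low value there may thus come from the division of reads between the hsp-16 copies.

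DMSO replicate 1 stood apart in heat shock genes (6.61), pharyngeal genes (1.75), lys-7 (180), cyp-34A9 (14.2), dhs-26 (0.733) and hsp-16.48 (0.628), a member of the heat shock list whose reads are shared with hsp-16.49 (18 counts, against 1, 1 and 0 in the other DMSO libraries). DMSO replicate 2 did so in ram-2 (27.3), unc-119 (25.9), ZK180.5 (20.6), Y47D7A.13 (18.3), col-90 (7.58) and ugt-14 (2.83), and DMSO replicate 3 in ribosomal RNA (1.084%), hsp-3 (1331), noah-1 (190) and mrpl-50 (61). Genipin replicate 2 stood apart in genes with a count (17470), mrps-7 (17.5) and msp-55 (0.298), and genipin replicate 3 in the intracellular pathogen response (1.74), rpl-11.2 (444), noah-1 (213) and Y47D7A.13 (10.7).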

How the results depend on the processing

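The subtraction of bromhexine counts from genipin replicate 1, the summed hsp-16 copies and the splits without genipin replicate 1 were chosen after the result was seen. No named gene or list called in the main analysis was called in the opposite direction. With the copies summed the genipin change went from 7.65 for hsp-16.48 alone to -0.21, which was not called, and the genipin calls turned from mostly higher (4 higher, 1 lower) to 3 higher and 8 lower without genipin replicate 3. Among the values of named genes over all alternatives, 15 of 3095 lost the call for bromhexine against DMSO, 28 of 418 for genipin and 70 of 2828 between the compounds, while 2, 1 and 19 gained one. Of 861 list values per comparison 56, 63 and 44 lost the call and 13, 10 and 8 gained one. Among the values of named genes called in neither the main analysis nor the alternative, 21 changed sign, and a gene can be counted under several alternatives.

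At an adjusted p under 0.01, where fewer genes pass by construction, bromhexine kept 3188 genes (1295 higher, 1893 lower), genipin 2 (2 higher, 0 lower), the direct comparison 2457 (855, 1602) and the overlap 2. At a minimum of 2-fold they kept 1412 (382, 1030), 3 (0 lower), 1259 (367, 892) and 3. For genipin DESeq2 gave 30 (14 higher, 16 lower), voom 2 (1 higher), no filter 17 (9, 8) and a fit of only the 8 libraries 3 (2 higher), and the cause was not tested. The overlap was 25 with DESeq2, 2 with voom, 16 without a filter and 3 with only the 8 libraries. It was 2 in every split of the DMSO libraries, and 2 to 3 without genipin replicate 1.

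The correlation r was 0.354 with voom and 0.375 after subtracting 3.26% of bromhexine counts from genipin replicate 1, and the cause of the first was not tested. With split controls, which share no control error, it was 0.321, 0.237, 0.304, 0.312, 0.392 and 0.223, and in the 6 splits without genipin replicate 1 it was 0.184, 0.106, 0.178, 0.163, 0.242 and 0.107. The thresholds do not apply to r.

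Of the lists, camera with an estimated correlation called 0 up and 0 down in each comparison. The directional fry test called 0 up and 0 down for genipin, and the mixed one 39, 3 and 41 lists for the 3 comparisons. The 2 camera runs differ only in the correlation between genes of a list. The preset was 0.01, while the estimates had a median of 0.18 over the lists in each comparison, so the preset lay far below them. The cause of the differences with fry was not tested.

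With the replicate number as a replicate block, bromhexine gave 5444 calls, the direct comparison 4542 and genipin 5 with 2 lower. Of the genipin calls, clec-68, cyp-13A5 and hsp-16.48 were shared with the fit without the block. Under the block 4 of 41 lists lost their call for bromhexine against DMSO, and the list calls of the other comparisons stayed the same. Whether the numbers pair samples stays open: same-number correlations over 0.1 held for 0 of 4 pairs of bromhexine and DMSO and 0 of 4 of bromhexine and genipin, but for 3 of 4 of genipin and DMSO (0.3, 0.25 and 0.18, and 0.02 for replicate 1).

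Leaving out each library in turn gave 4239 to 6254 genes for bromhexine (1856 to 2921 higher, 2383 to 3333 lower), 2 to 11 for genipin (2 to 9 higher, 0 to 8 lower) and 3301 to 5672 between them (1301 to 2578 higher, 2000 to 3094 lower). The overlap ran from 2 to 11 and r from 0.234 to 0.54. Lists called up and down ran from 9 to 17 and 3 to 4 for bromhexine, 4 to 8 and 5 to 8 for genipin, and 12 to 18 and 4 to 5 between them.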

Other observations

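No test in this part was chosen after its result was seen. Of the lists not described above, none was called with bromhexine. Among 9 genes of the hypoxia and hydrogen sulfide response 0 rose and 2 fell (the same over the list alone, adjusted p = 0.772, median 0.02, mean -0.07). Of 11 metal response genes 3 rose and 3 fell (4 and 3 over the list alone, adjusted p = 0.263, median -0.11, mean 0.06). Among them cdr-1, a cadmium-responsive gene, rose 10-fold (3.32 ± 0.22, from 9.93 to 99.6 CPM, n = 4), while the metallothionein gene mtl-2 fell by 0.34 (± 0.09). Of 22 genes of the intracellular pathogen response 1 rose and 6 fell (1 and 5 over the list alone, adjusted p = 0.382), with eol-1 at -1.57 ± 0.25, the cullin gene cul-6 at -1.15 ± 0.19 and pals-22 at -0.71 ± 0.17. In one-carbon metabolism 4 of 21 rose and 4 fell (the same over the list alone, adjusted p = 0.422), with sams-5 at -1.13 ± 0.23, mmcm-1 at 0.33 ± 0.07 and ahcy-1 at 0.27 ± 0.08.

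Genes of DNA damage and apoptosis moved little, with 1 of 15 higher and 2 lower (0 and 1 over the list alone, adjusted p = 0.817): ced-4 fell by 0.33 (± 0.06), and the calls on ced-3 (0.25 ± 0.09, adjusted p = 0.0312) and egl-1 (-0.65 ± 0.23, adjusted p = 0.0385) were close to the threshold. Of 39 histone genes 3 rose and 4 fell (1 and 4 over the list alone, adjusted p = 0.546), with the variant histone gene his-72 at -0.67 ± 0.11, his-24 at -0.57 ± 0.16 and his-41 at -0.39 ± 0.10. Of 68 mitochondrial ribosomal proteins 1 rose and 8 fell over all genes (0 and 0 over the list alone, adjusted p = 0.34), with mrps-11 at -0.28 ± 0.08, mrpl-50 at -0.29 ± 0.08 and mrps-7 at -0.30 ± 0.09. The 26 lists not called with genipin had medians between -0.08 and 0.16 and adjusted p from 0.102 to 0.992. Median, mean and direction of the test differed in sign for C-type lectins (-0.03, 0.01, down), the intracellular pathogen response (-0.06, 0.01, down), metal response (-0.08, -0.07, up), histones (-0.01, 0.09, up) and mitochondrial chaperones (0.02, -0.01, down).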
